A study of Amycolatopsis mediterranei U32 with 4 samples.

How the data were processed

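RNA from 4 cultures of *Amycolatopsis mediterranei* U32 was sequenced, 1 library for each combination of 24 or 48 h with 0 or 80 mM added nitrate. Per the labels' protocols, cells were pelleted and frozen, RNA was extracted with Trizol, and cDNA libraries followed standard Illumina protocols. Per the submitters' processing notes, Bowtie2 2.0.5 and bedtools 2.16.1 were used, with no role stated for either. How strands and reads with several matches were handled, and which annotation version was used, is not given in the sources used here. Reads of overlapping genes and of antisense partners therefore cannot be told apart, and 2223 pairs of neighbouring protein-coding genes overlap. Copies of the ribosomal RNA operon share reads, so their values are uncertain.

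The deposited table of all genes gives raw read counts per gene, per the file headers. It also gives RPKM, reads scaled by gene length and library total, which the authors computed from those counts. From the values, the library totals behind the RPKM were 17101379, 16514363, 17564533 and 24162480 reads for 24 h without, 24 h with, 48 h without and 48 h with nitrate, and 88.1, 89.6, 84.0 and 86.1% of those totals were in genes. All protein-coding gene lengths are multiples of 3, so they are coding lengths. A smaller deposited table gives a class for 256 genes (carbon metabolism 167, nitrogen metabolism 34, rif cluster 55) and ratios that the authors made from their RPKM, per the file headers. All 1024 of these ratios equalled the RPKM ratios of the named libraries within a relative tolerance of 1e-06. The criterion of the classes is not given in the sources used here. A further 12 columns of per-sample values match no sample and were not used.

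Sample groups were taken from the medium and time labels. Ratios were computed on log2(RPKM + 1), which understates differences of low genes. Genes with 10 RPKM or more in at least 1 of the 2 libraries were compared, and a ratio of at least 2-fold was counted. No model was fitted and no p-value computed, since each group has 1 library. An additive model of nitrate and time over all libraries was not run. Folds given with an interval are RPKM ratios without the added 1. Their 95% Clopper-Pearson intervals come from the reads of both libraries and the authors' library totals. PCR copies are not independent molecules, so these intervals and the limits from a count of 0 cover counting error only. Depth was 14746754 to 20812169 reads in genes per library. Ribosomal RNA genes took 0.00917 to 0.0352% of these reads.

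Gene lists, 31 in number, were fixed from product names and gene symbols before the data were examined. Each list's median was placed among those of 10000 random lists of the same size, matched on mean expression in 20 bins. Some patterns caught other genes. The ATP synthase list holds *kdpA*, *kdpB* and *kdpC*. The TCA and glyoxylate list holds *leuA* and *leuB*, and the ammonium assimilation list holds *argA* and *argJ*. Genes named in the text follow a rule fixed beforehand. For both nitrate comparisons these were the 10 highest and 10 lowest log2 ratios, and for both time comparisons the 5 highest and 5 lowest. Up to 4 members per list with the largest ratios, and all members of the rifamycin and nitrate assimilation lists, could also be named. Ribosomal and transfer RNA genes were left out of the top lists. Exceptions are marked where they occur.

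Alternatives were pseudocounts of 0.1 and 10, no filter, a filter of 50 RPKM and a median log2 ratio set to 0. Others were equal totals without ribosomal RNA and the 20 highest genes of any library, and CPM for named genes. CPM scales counts by each library's reads in genes, without gene length, so its total also differs from that behind the RPKM. The counting of genes was tested on simulated data, in which 200 genes were changed 4-fold or 0.25-fold. They were drawn only from genes with at least 4 times the 10 RPKM of the filter in the comparison's denominator library. Recovery of genes nearer the filter, or of changes nearer 2-fold, was therefore not tested. Across the 4 comparisons, 5307 to 5614 genes were run, 100% of the changed genes were recovered in each direction, and at most 1 unchanged gene was counted. The intervals held the true fold for 96% of the changed genes for nitrate at 24 h and at 48 h, 93.5% over time without nitrate and 97.5% over time with nitrate. These simulations hold counting error only. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.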

Results

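Messenger RNA was sequenced from *Amycolatopsis mediterranei* U32, an actinomycete that makes the polyketide antibiotic rifamycin, after growth in Bennet medium with or without 80 mM added nitrate. Cells were collected at 24 h, given in the labels as mid-log phase, and at 48 h, given as stationary phase. The design had 4 groups with 1 library each: 24 h without nitrate, 24 h with nitrate, 48 h without nitrate and 48 h with nitrate. The reads assigned to the 9291 annotated genes numbered 15067615, 14789585, 14746754 and 20812169 in that order. At this depth the limit that a count of 0 allows, 3 reads, corresponded to 0.175, 0.182, 0.171 and 0.124 RPKM for a gene of 1 kb. With 1 library per group there was no replicate error, and no test between conditions was run. Ratios are therefore described by size, and the 95% intervals (exact Clopper-Pearson) cover counting error only. A gene was counted as higher or lower when its RPKM values, each with 1 added, differed at least 2-fold and at least 1 of the 2 libraries had 10 RPKM or more. Positions are 1-based coordinates on the U32 chromosome as the deposited table gives them, and all named genes are protein-coding.

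The first comparison was between the 24 h libraries with and without added nitrate. The labels do not name the cation added with the nitrate, and no group had another salt instead. Effects of nitrate therefore cannot be told apart from those of its cation or of osmolarity, at either time. Throughout, "with nitrate" names the medium and not the cause. The genes of the rifamycin cluster had similar levels in both media: none of the 20 genes with rif names or rifamycin products was 2-fold apart, and their median log2 ratio was -0.05. The gene with the largest ratio among them was *rifA* (AMED_0617, 629641 to 643848, plus strand), which encodes a subunit of the rifamycin polyketide synthase. It had 1114 RPKM with nitrate and 713 RPKM without, a 1.56-fold difference (1.55 to 1.57). The *nas* operon, which encodes assimilatory nitrate and nitrite reductase and a nitrate transporter, had few reads in both 24 h libraries. *nasB* (AMED_1124, 1181341 to 1183863, plus strand) had 57 reads with nitrate and 30 without, and *nasK* (AMED_1123, the transporter) had 58 and 25. RPKM ratios from AMED_1121 to AMED_1126 were all above 1, from 1.55 for *nasD* (AMED_1125) to 3.31 for *nasA* (AMED_1121). All lay at or below 3.47 RPKM, under the filter. The ammonium transporter gene *amtB* (AMED_1941) was 3.21-fold higher with nitrate (2.63 to 3.95), and the P-II protein gene *glnB* (AMED_1942) was 2.10-fold higher (1.64 to 2.71). These were the 2 higher members of the ammonium assimilation list, which had 2 lower among 19 measured genes and a median log2 ratio of -0.23, at the 3.22 percentile of matched random lists. The authors' nitrogen class had 1 of 24 measured genes higher and 7 lower, with a median of -0.46, or -0.24 with no filter on low values.

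Of 5836 genes compared at 24 h, 322 were at least 2-fold higher and 397 at least 2-fold lower with nitrate, and the median log2 ratio over all of them was 0.07. The highest 10 included 4 neighbouring genes annotated as an ABC transporter and its surroundings. AMED_7065, AMED_7066, AMED_7067 and AMED_7068 had log2 ratios of 4.20, 4.39, 4.37 and 4.40. Also among the highest were *betB* (AMED_7558, betaine aldehyde dehydrogenase) at 3.84, the amino acid permease gene AMED_7559 at 4.25 and *betA* (AMED_7560, choline dehydrogenase) at 3.61. The enzymes encoded by *betA* and *betB* convert choline to the osmoprotectant glycine betaine. The membrane protein genes AMED_5721 and AMED_5732 and the regulator gene AMED_5729 completed the list with 3.35, 4.06 and 3.21. The lowest were AMED_3586 (polysaccharide deacetylase) and its neighbour AMED_3585, with log2 ratios of -6.50 and -6.10, then AMED_8638 (UDP-N-acetylmuramyl tripeptide synthase) and AMED_8637 (glutamine amidotransferase), with -5.36 and -4.99. The remaining 6 of the 10 lowest lay in 1 aromatic polyketide gene region and included *actV* (AMED_5432, polyketide cyclase/dehydratase), AMED_5437 (polyketide synthesis cyclase) and *actI* (AMED_5433, 3-oxoacyl-ACP synthase), with -5.04, -5.05 and -4.88. The others were AMED_5429, AMED_5436 and AMED_5440, with -4.93, -5.04 and -4.84. These lie in AMED_5407 to AMED_5450 (5997315 to 6044374), a run of 44 genes bounded from these ratios, each at least 4-fold lower with nitrate, with a median log2 ratio of -3.98.

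**Figure D1:**
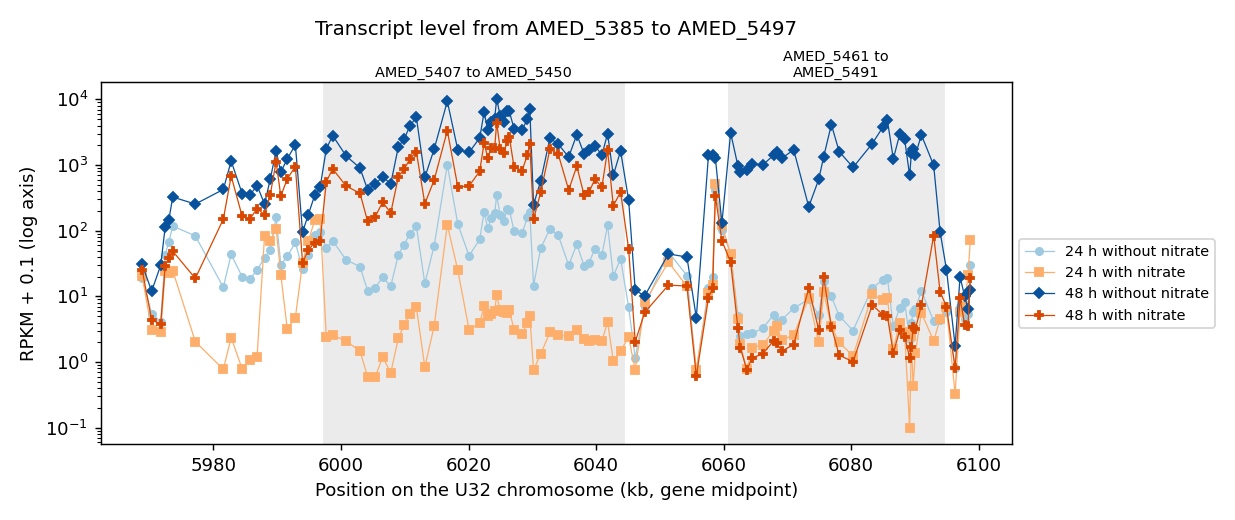
RPKM plus 0.1 (log axis) of each gene from AMED_5385 to AMED_5497 against the gene's midpoint on the U32 chromosome, 1 line per library, with AMED_5407 to AMED_5450 and AMED_5461 to AMED_5491 shaded. In the first shaded region the median was 66.3 RPKM at 24 h without nitrate, 2.84 at 24 h with nitrate, 2284 at 48 h without nitrate and 817.0 at 48 h with nitrate.

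Among the lists fixed by annotation at 24 h, ribosomal protein genes had a median log2 ratio of 0.55, above every one of 10000 random lists matched on expression. Of 59 measured, 3 were at least 2-fold higher and none was lower. Transfer RNA genes, a group added after the data were seen, had a median of 0.70, with 16 of 41 higher and none lower, and took 0.0820% of the reads in genes without nitrate and 0.173% with nitrate. The ATP synthase list had a median of 0.72, at the 99.8 percentile, with none of 9 measured genes 2-fold apart. Amino acid and peptide uptake genes had a median of 0.38, with 5 of 51 higher and 4 lower. Urea and purine nitrogen genes had -0.57, at the 0.48 percentile, with 1 of 11 higher and 1 lower. TCA and glyoxylate cycle genes had a median of -0.26, or -0.08 with no filter on low values, and glycolysis genes -0.08. These percentiles describe the libraries, and genes of 1 operon are not independent members of a list.

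At 48 h the genes of the rifamycin cluster were far higher with nitrate than without. The list of 20 genes with rif names or products, fixed beforehand, had a median log2 ratio of 5.66, above all 10000 matched random lists, and all 20 were higher. The region from AMED_0613 to AMED_0655 (626181 to 716872) was bounded from these ratios, as a run of 43 neighbouring genes each at least 4-fold higher, so its count follows from that choice. Its log2 ratios ran from 2.94 to 10.53, with a median of 8.01. *rifA* had 153694 reads with nitrate and 100 without, a 1117-fold difference in RPKM (919 to 1373). The gene for AHBA synthase, *rifK* (AMED_0627, 684231 to 685397, plus strand), which makes the aminohydroxybenzoate starter unit of rifamycin, was 466-fold higher (366 to 603). *rifR* (AMED_0648), *rifT* (AMED_0614) and *rifB* (AMED_0618) were 832-fold (533 to 1383), 578-fold (366 to 976) and 941-fold (789 to 1133) higher. The cytochrome P450 gene AMED_0637 (694626 to 695891, minus strand) had 143302 reads with nitrate and 68 without. At the edge of the region, AMED_0655, a LuxR family regulator gene chosen after its values were seen, had 753 RPKM without nitrate and was 7.67-fold higher with nitrate (7.55 to 7.80). The authors' rif class of 55 genes had 44 higher and none lower. The other 12 genes of that class, AMED_0601 to AMED_0612, had a median of 0.74, with 1 of 12 higher.

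**Figure D2:**
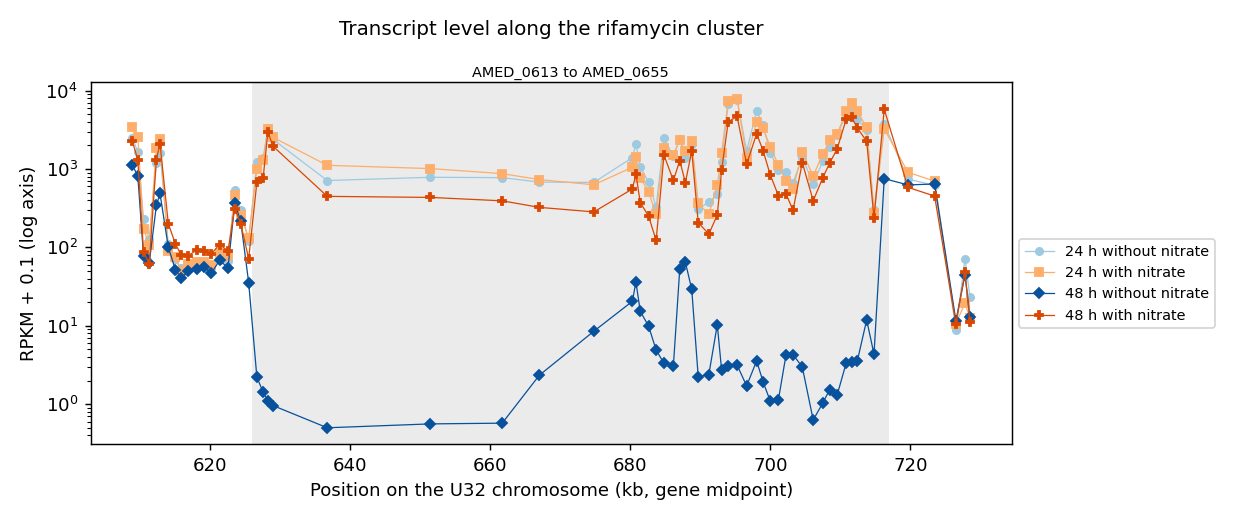
RPKM plus 0.1 (log axis) of each gene from AMED_0595 to AMED_0660 against the gene's midpoint in kb on the U32 chromosome, 1 line per library, with the region AMED_0613 to AMED_0655 shaded. Within the shaded region the library of 48 h without nitrate had a median of 3.01 RPKM, against 1398, 1525 and 774 RPKM at 24 h without, 24 h with and 48 h with nitrate.

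Of 9 measured nitrate and nitrite assimilation genes, 7 were at least 2-fold higher with nitrate at 48 h and none was lower, with a median log2 ratio of 7.42. *nasK* was 779-fold higher (563 to 1112) and *nasB* 1189-fold higher (799 to 1856). *nasA* (AMED_1121, 1176479 to 1178527, plus strand), the catalytic subunit of nitrate reductase, had 9625 reads with nitrate and 5 without. *nasC* (AMED_1122) had 8008 and 2 reads, a ratio of 2911 with a wide counting interval from 805 to 24038, and *nasD* (AMED_1125) had 6403 and 10. The nitrite genes outside the operon, *nirC* (AMED_5747) and *nirA* (AMED_6656), were 73.8-fold (58.4 to 94.8) and 17.3-fold (15.9 to 18.8) higher. The regulator gene *nasT* (AMED_6148) had a log2 ratio of -0.56. In the ammonium assimilation list, 7 of 20 genes were higher and 3 lower, with a median of 0.33 at the 79.5 percentile. The higher members included *amtB* at 5.90 and *glnB*, 33.4-fold higher (27.9 to 40.4), with *glnD* (AMED_1943, which encodes the enzyme that uridylylates P-II) at 4.44, and glutamine synthetase *glnA* (AMED_1229), chosen after its values were seen, at 3.70. Alanine dehydrogenase *ald* (AMED_7939) went the other way, at -5.31, with 21312 reads without nitrate and 714 with. The nitrogen regulator gene *glnR* (AMED_9008), chosen after its values were seen, had 280 RPKM with nitrate and 267 without. Urea and purine nitrogen genes had none of 11 higher and 2 lower, with a median of 0.05 at the 38.2 percentile, or -0.12 with the median of all genes set to 0. The authors' nitrogen class had 15 of 32 genes higher and 6 lower, with a median of 0.65, or 0.28 with no filter on low values.

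**Figure D3:**
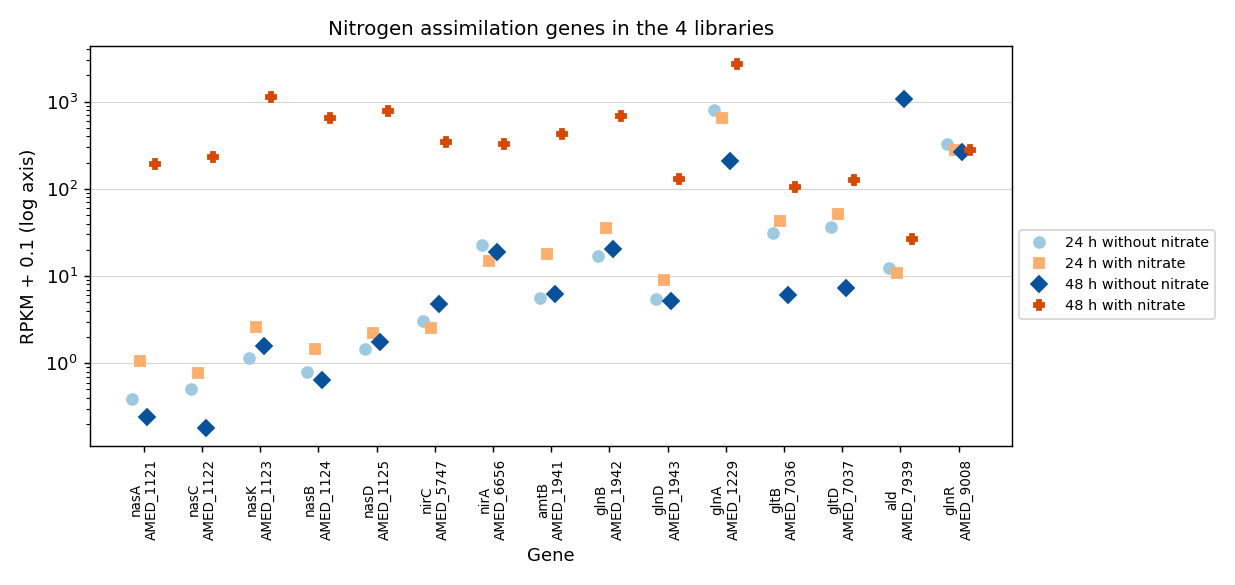
RPKM plus 0.1 (log axis) of 15 nitrogen genes, 1 symbol per library. The 5 *nas* genes lay at 194 to 1147 RPKM at 48 h with nitrate and at or below 2.52 RPKM in the other 3 libraries.

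In the phosphate list at 48 h, 11 of 13 measured genes were higher with nitrate and 1 lower, with a median of 3.46, above all matched random lists. Over all 26 members, with no filter on low values, the median was 0.85. The PiT family transporter gene AMED_1273 was 64.1-fold higher (57.3 to 71.8), the alkaline phosphatase gene *phoD* (AMED_6715) 87.0-fold (66.1 to 117), and *pstS* (AMED_9006), which encodes the phosphate-binding protein of the Pst transporter and was chosen here after its values were seen, 11.7-fold (11.4 to 12.0). Ribosomal protein genes had a median of 1.45, with 39 of 59 higher and 3 lower. Transfer RNA genes had a median of 1.40, with 24 of 41 higher and 3 lower, and took 0.0346% of the reads in genes without nitrate and 0.109% with nitrate. The ATP synthase list had 8 of 12 higher and 3 lower. Its 3 lower members were not ATP synthase genes but *kdpA*, *kdpB* and *kdpC* (AMED_1893 to AMED_1895), which encode a potassium pump and had log2 ratios of -8.90, -9.08 and -9.00. *atpB* (AMED_7781) was 13.1-fold higher (12.5 to 13.7). In the chaperone list, 9 of 28 were higher and 4 lower. The chaperonin gene AMED_8554 (GroEL) was 19.9-fold higher (19.5 to 20.2), and another GroEL gene, AMED_4331, was 151-fold lower (118 to 196).

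Among the genes lower with nitrate at 48 h, a separate region stood apart. All of the 10 lowest log2 ratios fell in AMED_5461 to AMED_5491 (6060811 to 6094543), a run of 29 genes bounded from these ratios, each at least 4-fold lower with nitrate, with a median of -8.87. *cydA* and *cydB* (AMED_5474 and AMED_5475), which encode the cytochrome bd terminal oxidase, had 4144 and 1610 RPKM without nitrate and 3.38 and 1.18 RPKM with nitrate, log2 ratios of -9.89 and -9.53. Universal stress protein genes AMED_5478, AMED_5480 and AMED_5483 had -9.23, -9.10 and -9.53, and the acyl-CoA synthetase gene AMED_5470 had -9.28. The hypothetical protein genes AMED_5468, AMED_5479, AMED_5482 and AMED_5485 had -9.13, -9.67, -9.54 and -9.18. The neighbouring region AMED_5407 to AMED_5450 had a median of -1.56, with 39 of 44 genes at least 2-fold lower, and took 13.5% of the reads in genes without nitrate and 4.65% with nitrate. The sensor kinase gene *devS* (AMED_5471) and the phosphoketolase gene AMED_5477, both chosen after their values were seen, had -4.03 and -8.00. NADH dehydrogenase genes were lower with nitrate in 15 of 16 cases, with a median of -1.75, below all matched random lists, and *nuoA* (AMED_0520) was 4.02-fold lower (3.84 to 4.21). Glycolysis and gluconeogenesis genes had 7 of 29 lower and 2 higher, with a median of -0.63, or -0.14 with no filter on low values.

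In all, 1232 of 5956 genes were at least 2-fold higher and 938 at least 2-fold lower with nitrate at 48 h. The median log2 ratio over these genes was 0.17, and with it set to 0 the counts were 988 higher and 1106 lower. The 10 genes with the highest log2 ratios all lay in the rifamycin region. They were AMED_0615, AMED_0637, AMED_0616, AMED_0651, AMED_0650, AMED_0636, AMED_0649, AMED_0652, AMED_0639 and *rfbC* (AMED_0640), with log2 ratios from 9.25 to 10.53. This ranking depends on the constant added to each RPKM. In RPKM ratios without it, *nasC* (2911), *nasA* (1399) and *nasB* (1189) exceeded AMED_0652 (978), *rfbC* (939) and AMED_0639 (811).

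Over time without nitrate, from 24 h to 48 h, the rifamycin list was lower in all 20 genes, with a median log2 ratio of -6.50. The 43 genes of the region bounded at 48 h, which shares a library with this comparison, were also lower, with a median log2 ratio of -8.63. AMED_0637 was 2485-fold lower at 48 h (1960 to 3200) and *rifA* 1779-fold lower (1463 to 2187). The 5 lowest were AMED_0637, AMED_0636, AMED_0615, AMED_0651 and AMED_0616, with log2 ratios from -10.87 to -10.32. Ribosomal protein genes had a median of -1.65, which was -1.27 relative to all genes, with 42 of 59 lower and 1 higher. Transfer RNA genes had a median of -0.95, with 19 of 41 lower and 4 higher. NADH dehydrogenase genes had a median of 3.38, with 15 of 16 higher. Sugar uptake genes had 0.91, with 25 of 52 higher and 4 lower, and amino acid and peptide uptake genes had 0.63, with 19 of 52 higher and 7 lower. With no filter on low values, over all 134 and 91 members, these medians were 0.19 and 0.12. Among single genes, the highest were AMED_5482, *cydA*, AMED_5468, AMED_5485 and the type IV pilus gene AMED_4453, with log2 ratios of 8.61, 8.57, 8.32, 8.28 and 8.20. AMED_4453 had 2350 reads at 48 h and 2 at 24 h, a ratio of 1144 with a counting interval from 316 to 9452. *ald* was 89.8-fold higher at 48 h (78.9 to 103). In the osmoprotection list, 3 of 24 genes were higher and 6 lower, with a median of -0.71. Its member with the largest ratio, the *betB* gene AMED_1201, was 283-fold higher at 48 h (121 to 873). The ectoine synthesis genes *ectC* (AMED_8595) and *ectD* (AMED_8594), which make osmoprotectants, were 38.5-fold (33.7 to 44.1) and 35.4-fold (31.8 to 39.6) lower. Of 6018 genes, 898 were higher and 1598 lower, so that 36.0% of these were higher. The median log2 ratio over all genes was -0.38. With it set to 0, 1244 were higher and 982 lower, and 55.9% were higher.

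Over time with nitrate, the rifamycin region had a median log2 ratio of -0.83, with 15 of 43 genes at least 2-fold lower at 48 h and none higher. *rifA* was 2.49-fold lower (2.47 to 2.50). Nitrate assimilation genes were higher at 48 h in 7 of 9 cases and lower in 1, *nasT* at -1.28, with a median of 6.66. *nasB* was 471-fold higher (363 to 622). Phosphate genes were higher in 10 of 14 cases and lower in 1, with a median of 3.66, and ammonium assimilation genes in 10 of 20 cases, with 3 lower and a median of 0.98. With no filter on low values these medians were 0.72 and 0.58. NADH dehydrogenase genes were higher at 48 h in this medium too, in 14 of 15 cases with 0 lower, and had a median of 1.64. The 5 highest genes lay in the aromatic polyketide region. They were AMED_5440, AMED_5441, AMED_5429, *actI* and AMED_5437, with log2 ratios of 8.87, 8.73, 8.61, 8.56 and 8.50. The 5 lowest were *paaD* (AMED_1567), *pdhB* (AMED_7570, pyruvate dehydrogenase), *paaB* (AMED_1565), *paaA* (AMED_1564) and *paaC* (AMED_1566), with -7.06, -6.87, -6.66, -6.59 and -6.59. The *paa* genes belong to phenylacetate breakdown. Of 5976 genes, 675 were higher and 973 lower, so that 41.0% of these were higher, and the median log2 ratio over all genes was -0.27. With it set to 0, 897 were higher and 587 lower, and 60.4% were higher.

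**Figure D4:**
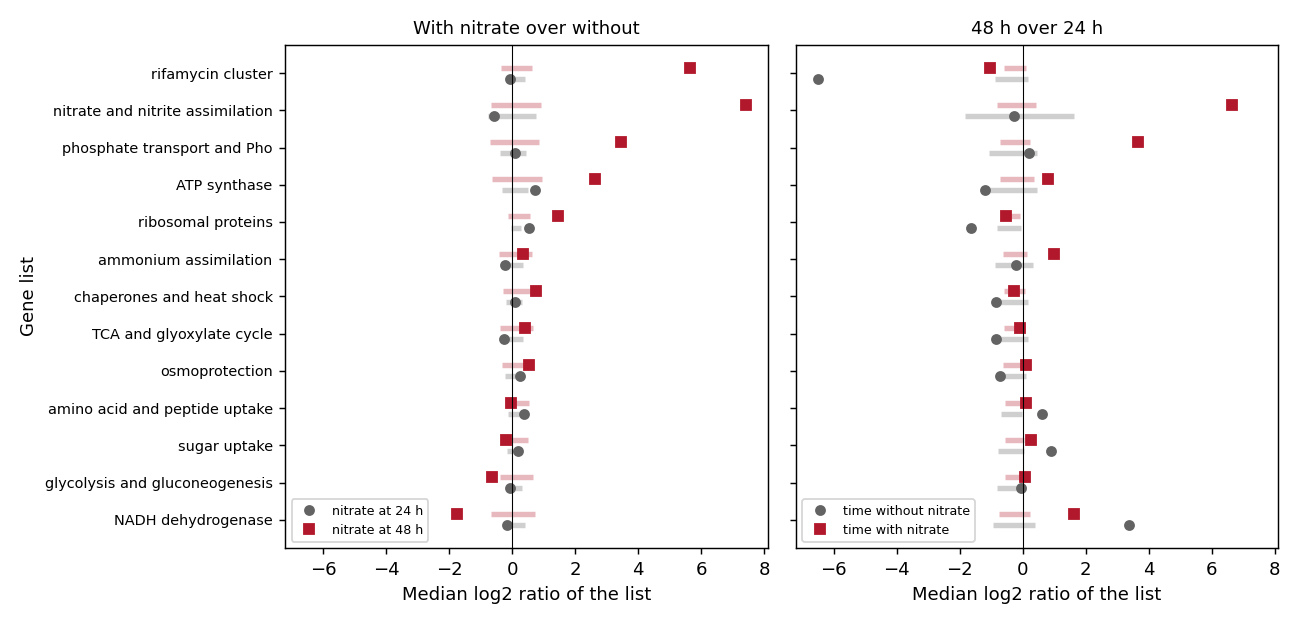
Median log2 ratio of 13 gene lists in the 4 comparisons, left with nitrate over without and right 48 h over 24 h. Points are list medians and the pale bars the central 95% of medians of 10000 random lists matched on expression. The rifamycin cluster lay at -0.05 and 5.66 for nitrate at 24 h and 48 h, and at -6.50 and -1.04 over time without and with nitrate.

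The difference between the nitrate ratios at 48 h and at 24 h was described by size only and was not tested. Its median was 5.85 on the log2 scale over the rif list and 6.82 over the nitrate assimilation list. For single genes it was 8.23 for *nasB*, 7.68 for *rifA* and 4.37 for *amtB*. Both nitrate comparisons used separate libraries. Among the 5378 genes measured in both, 93 were at least 2-fold higher in both, where independent lists of those sizes would share 46.4, and 160 were lower in both, where independent lists would share 44.9. A further 47 were lower at 24 h and higher at 48 h, against 76.8 for independent lists, and 12 were higher and then lower, against 27.1. Of the 160 genes lower in both, 39 lay in AMED_5407 to AMED_5450, where all 44 genes were lower at 24 h and 39 at 48 h. The Spearman correlation of both ratios across genes was 0.32, and genes are not independent replicates. The comparisons over time also share no library, and 285 genes were higher and 491 lower at 48 h in both media, against 62.6 and 240.4 for independent lists. Nitrate at 48 h and time without nitrate, by contrast, share the library of 48 h without nitrate, so their large differences are not separate evidence. The same holds for nitrate at 48 h and time with nitrate, which share the library of 48 h with nitrate, as for the *nas* genes. It also holds for nitrate at 24 h and either comparison over time, which share a 24 h library, as for AMED_5407 to AMED_5450.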

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

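The tests in this part were chosen only after the results were seen, apart from the rule that singled out the genes. That rule took genes whose nitrate ratio was at least 2-fold in opposite directions at 24 h and 48 h, among 40 genes named by size and 34 gene lists. It found 4 genes, and the difference between times was not tested, since each group has 1 library. The filter of 10 RPKM was asked only in the comparison that named a gene, and all 4 were named at 24 h. Their 48 h ratios were not filtered and can rest on values below 10 RPKM in both libraries. Of the 34 lists, 19 had medians of opposite sign at 24 h and 48 h, but none reached 2-fold in both directions. AMED_3585 had a log2 ratio of -6.10 at 24 h and 2.07 at 48 h, a difference of 8.17. Its neighbour AMED_3586, a polysaccharide deacetylase gene, had -6.50 and 2.15, a difference of 8.66. AMED_8637, a glutamine amidotransferase gene, had -4.99 and 1.97, a difference of 6.96, with 3 reads at 48 h without nitrate. The neighbouring AMED_8638, a UDP-N-acetylmuramyl tripeptide synthase gene, had -5.36 and 2.82, a difference of 8.18. These pairs had most reads at 24 h without nitrate, with 13071 reads for AMED_3585 and 16560 for AMED_8638, against 23 and 17 at 48 h without nitrate.

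The first pattern weighed was the low level of AMED_0613 to AMED_0655 at 48 h without nitrate. Lower depth is argued against, since the reads in genes were 0.979 times those at 24 h without nitrate. Loss of the cluster's DNA from part of the cells, as the only cause, would lower the genes by a common factor. Their log2 ratios over time without nitrate instead ranged from -10.87 to -2.32, a range of 8.55. Leaving out the edge gene AMED_0655, the RPKM ratios still ran from 0.000299 for AMED_0615 to 0.0462 for *rifN* (AMED_0630). Loss from all cells would leave only background, and the ratios would then follow the 24 h levels. Those were 296 to 7600 RPKM without nitrate, so the range cannot exclude loss from all cells. An event in this single culture cannot be told apart from an effect of the condition, because the group has 1 library.

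The second pattern was the high level of the *nas* genes at 48 h with nitrate but not at 24 h with nitrate. A mislabelled 24 h library, taken from a culture without nitrate, stays open: the 10 genes highest with nitrate at 24 h had a median log2 ratio of 3.95 for nitrate at 48 h, and 7 of them were at least 2-fold higher. Those 10 genes lie at few loci, and the 10 lowest at 24 h had a median of -0.88 at 48 h, short of the 2-fold asked of both sides, a bound set after these values were seen. A response to low nitrogen at 48 h with nitrate stays open, since 46.2% of 13 ammonium assimilation genes matched by symbol were at least 2-fold higher, 6 higher and 1 lower, between the bounds set for either outcome.

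The third pattern was the high level of AMED_5461 to AMED_5491 at 48 h without nitrate. Reads from another organism were not tested and stay open. Low oxygen in that culture stays open, since the 7 measured genes of the cytochrome oxidase list, which leaves out *cydA* and *cydB*, had a median of 0.53 for nitrate at 48 h, between the bounds set for either outcome.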

How the results depend on the processing

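All alternatives here were planned, and where values moved the cause was not tested unless stated. With a pseudocount of 10, nitrate at 24 h gave 169 genes higher and 250 lower, and time with nitrate gave 603 lower. With a filter of 50 RPKM, which compares fewer genes by construction, the counts were 156 higher and 223 lower for nitrate at 24 h, 728 and 571 for nitrate at 48 h, 549 and 922 over time without nitrate, and 407 and 557 over time with nitrate. With the median log2 ratio set to 0, 982 genes were lower over time without nitrate and 587 over time with nitrate. The median of the rif list for nitrate at 48 h was 5.91 with a pseudocount of 0.1, 4.57 with 10 and 5.49 with the median set to 0. The nitrate assimilation median was 8.78 with 0.1 and 4.59 with 10. The differences between times were 6.17 and 4.64 for the rif list, and 8.18 and 4.55 for nitrate assimilation, with 0.1 and 10. Of 136 list medians, 17 changed sign with the median set to 0 and 11 with no filter on low values. For named genes, 115 of 408 log2 ratios moved beyond their counting interval with CPM in place of RPKM, and none of those at least 2-fold apart changed sign. Gene length cancels in a ratio between libraries before a constant is added. These moves therefore reflect the constant added on another scale and the other total. They do not show that scaling by gene length changes the folds. Depth limits genes with few reads, such as *nasC* and AMED_8637, whose ratios have wide counting intervals.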

Other observations

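The search for runs of neighbouring genes in this part was chosen only after the data were seen. At 48 h, 24 neighbouring genes from AMED_6224 to AMED_6247 (6877069 to 6920583) were all higher with nitrate, with a median log2 ratio of 5.65. Their median was 6.44 RPKM without nitrate and 372 RPKM with nitrate. In the other direction, AMED_4322 to AMED_4331 (10 genes) had log2 ratios from -7.61 to -3.37, and AMED_4447 to AMED_4457 (11 genes), which hold the pilus gene AMED_4453, from -8.05 to -4.26 with a median of -5.91. AMED_1880 to AMED_1898 (18 genes), which hold the *kdp* genes of potassium uptake, had log2 ratios from -9.08 to -2.16, with a median of -3.41. The 7 genes from AMED_7775 to AMED_7781, which hold *atpB*, had a median of 3.38. The phenylacetate genes AMED_1559 to AMED_1569 were lower at 48 h in both media, with medians of -4.66 without and -5.45 with nitrate.

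Runs of at least 6 neighbouring genes, each at least 4-fold apart in 1 direction, numbered 4 for nitrate at 24 h, 15 for nitrate at 48 h, 23 over time without nitrate and 8 over time with nitrate. They held 67, 202, 310 and 101 genes. The longest had 44, 43, 49 and 45 genes, against 3, 5, 5 and 5 in 1000 shuffles of gene order. Shuffling also separates the genes of operons, so this contrast shows only that genes 4-fold apart lay together.

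One hypothesis, with its prediction written before the result was seen, was that the culture at 24 h with nitrate may have been at an earlier stage than that at 24 h without nitrate, since AMED_5407 to AMED_5450 were lower with nitrate at 24 h and higher at 48 h in both media. At 48 h the region was also lower with nitrate, with a median log2 ratio of -1.56 and 39 of 44 genes at least 2-fold lower, which an earlier stage at 24 h alone does not cover. The hypothesis required a Spearman correlation across genes below -0.2 between the nitrate ratio at 24 h and the ratio over time without nitrate. Over all 5527 genes it was -0.21, past that bound, but these included the 44 genes that raised the hypothesis. Without them it was -0.195 over 5483 genes, short of the bound, and leaving them out was decided after the first value was seen. Both ratios share the library of 24 h without nitrate, which with counting error alone gave 0.457 in 100 simulations. These simulations held no other difference between libraries, so the size of this upward push in the data is not known. The hypothesis stays open, and genes are not independent replicates.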
